A study of Homo sapiens and Mus musculus with 20 samples.

How the data were processed

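Gene expression was measured by RNA sequencing in 20 libraries of 2 systems. KGN is an established human granulosa-like tumour cell line. The KGN cells were starved of serum for 24 h and then received 25 nM dihydrotestosterone (DHT), an androgen that cannot be aromatised to oestrogen, or ethanol for 12 h, with 5 libraries per group. In the other system, female mice aged 18 weeks received 29 µg of DHT or vehicle by intraperitoneal injection, and granulosa cells were pressed out of the ovaries 18 h later, again with 5 libraries per group. Per the labels' protocols, libraries were made from 100 ng of RNA with an oligo-dT based Illumina kit that does not mark the strand, and sequenced as single reads of 100 nt.

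The authors deposited, for each system, a table of raw read counts per gene symbol and a table of the same counts divided by a size factor. The submitters' processing notes name STAR 2.7.0f, Subread 1.6.4, featureCounts and DESeq2 1.22.1 with no order or role. They list the mouse build GRCm38 for all samples, and the human build is not given in the sources used here, so no coordinates are printed. The deposited size-factor signal was checked to be the counts divided by 1 constant per library. It was used for nothing else, and every test started from the deposited counts. The human table held 59087 genes, against 55453 in the mouse table.

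Total counts per library ran from 34540193 to 41079205 in KGN cells and from 22158445 to 29011691 in mouse cells. A count of 0 allows at most 3 counts, which is 0.0869 CPM (counts scaled by library size) in the shallowest KGN library and 0.135 CPM in the shallowest mouse library. Such floors cover counting error only. The closest libraries differed far beyond sampling noise, with a chi-square of 3.21 per gene in KGN cells and 4.95 in mouse cells, so no library was counted as a repeat of another. The labels do not say whether the libraries of a group came from separate cultures or separate animals. In both systems the p-values therefore measure only the spread between these libraries. For KGN cells that spread may be technical, and for mouse cells it need not be the spread between animals.

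Each system was tested alone with edgeR 4.0.16 (glmQLFit and glmQLFTest) after TMM scaling and filterByExpr, which left 15035 genes in KGN cells and 16689 in mouse cells. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change over the square root of its F statistic. Expression is given as CPM on TMM-scaled libraries, as mean ± SD with n = 5. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the 18 lists tested in KGN cells or the 25 tested in mouse cells; 1 more mouse list had too few members. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. The difference between the systems was tested as a treatment-by-species term over 10871 genes matched by symbol.

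The groups share numbers in their sample titles. The design fixed before the data were examined had no block, and the fit with the title number as a replicate block was planned beside it. Numbers were taken to pair the samples where each same-numbered pair deviated together from its group means with a correlation over 0.1. In KGN cells the correlations ran from 0.487 to 0.788, and all 5 treated libraries were closest to the control of their own number. The numbers therefore pair the KGN libraries, from the data alone, since no label states it. In mouse cells the correlations ran from -0.577 to 0.605, and the numbers were not taken as pairs. Both KGN fits had been run before this check, whose criterion does not use their calls, and the KGN results are given from both.

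The genes named were chosen by a rule fixed before the data were examined. It takes the 8 largest increases and decreases past the threshold with at least 5 CPM in a group, up to 3 changed members of each list, and, always, FKBP5, FOXL2, FSHR, LHCGR, CYP19A1, EZH2 and KDM6B. Where too few genes passed, it fills each direction up to 4 with the smallest unadjusted p. The design without the block gave no changed gene in KGN cells, so the same rule was applied to the blocked fit as well, a step decided after the data were seen. Other genes named were chosen after their values were seen. Some genes that the rule would name are not reported here, though they were kept in every test and count of changed genes. The kit does not mark strand, so reads from overlapping antisense genes cannot be told apart.

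Alternatives covered scaling, filters, DESeq2 1.42.0, voom with quality weights, a surrogate variable from sva 3.50.0, a minimum change of 1.2-fold, and each library left out in turn. Removal of trends on GC content and transcript length, each KGN pair left out, and 3 mouse libraries left out were added after the data were seen. Lengths and GC content came from GENCODE, matched by symbol for 98.6% of the tested KGN genes. The tests were run on simulated counts with 200 changed genes. At a 1.2-fold change, 72% of 50 changed genes were recovered in KGN cells with the block, 18% without it, 0% in mouse cells and 0% for the difference between the systems. At a 1.5-fold change, these were 94%, 74%, 24% and 38%. At 2-fold, 68% were recovered in mouse cells. With the KGN block, 6.35% of the simulated calls were false. Genes were drawn independently, without trends that many genes share between the libraries of a pair. These shares may therefore not carry over to the real libraries.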

Results

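RNA sequencing of 20 libraries compared DHT with control treatment in KGN cells and in mouse granulosa cells, the hormone-producing somatic cells of the ovarian follicle. Each of the 4 groups held 5 libraries. Total counts per library ran from 34540193 to 41079205 in KGN cells and from 22158445 to 29011691 in mouse cells. The series asks which transcripts respond to androgen in human and in mouse granulosa cells.

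In KGN cells DHT was followed by small changes that were visible once each treated library was set against the control of the same title number. With these pairs as a block, 200 genes rose and 68 fell among 15035 tested (edgeR quasi-likelihood test, adjusted p under 0.05). The median change among the 268 was 1.14-fold and 9 exceeded 1.5-fold. TMTC1 rose most among genes of moderate expression, from 15.04 ± 2.26 to 24.3 ± 3.17 CPM, a 1.62-fold change (log2 0.69 ± 0.05 SE, adjusted p = 4.99e-10 in edgeR, higher in 5 of 5 pairs). VCAM1, a cell adhesion molecule, rose 1.49-fold (log2 0.57 ± 0.04, adjusted p = 3.62e-09), and LGR5, a receptor for R-spondins, fell to 0.739 of its control level (log2 -0.44 ± 0.07, adjusted p = 6.08e-04). The fit planned as the main one, without the pairs, called 0 genes. There 366 genes had an unadjusted p under 0.05, fewer than the 752 expected by chance, while voom called 0 with 498 at that level and DESeq2 without the pairs called 2, TMTC1 and ERRFI1.

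For TMTC1 the pairs changed the error and left the size as it was, with a log2 change of 0.69 ± 0.11 without the pairs and 0.69 ± 0.05 with them. Of the 268 genes, 243 moved the same way in 5 of 5 pairs and 25 in 4 of 5. The paired fit favours genes whose pairs agree, so this count is no separate evidence. DESeq2 with the block called 175 genes, of which 169 were among the 268. With trends on GC content and transcript length removed within the blocked fit, 352 genes rose and 300 fell, and 260 of the 268 remained.

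**Figure D1:**
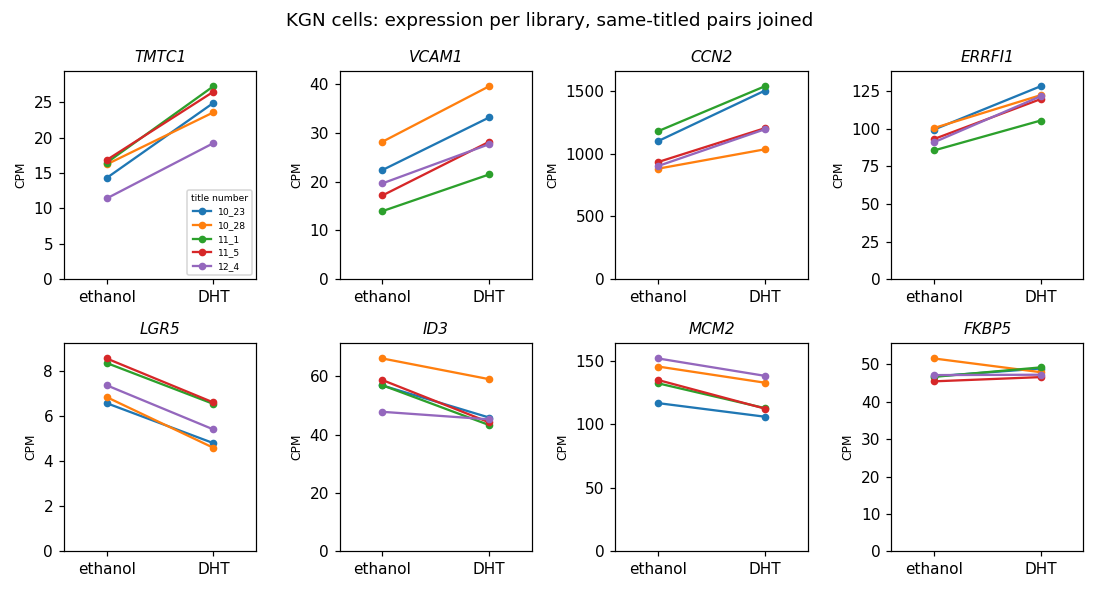
Expression in CPM (vertical axes, from 0) of 8 genes in the KGN libraries, ethanol on the left and DHT on the right, with a line joining each of the 5 same-titled pairs. TMTC1, VCAM1, CCN2 and ERRFI1 were higher with DHT in 5 of 5 pairs, LGR5, ID3 and MCM2 were lower in 5 of 5, and FKBP5 was higher in 4 and lower in 1.

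Genes that several steroid receptors share as targets moved up with DHT in KGN cells. Of 16 such genes tested, 5 rose, 0 fell and 11 did not pass. KLF9, a transcription factor, rose 1.36-fold (log2 0.45 ± 0.07, adjusted p = 1.88e-04 in the blocked edgeR fit). ERRFI1, a feedback inhibitor of the EGF receptor, rose 1.27-fold (log2 0.35 ± 0.03, adjusted p = 8.20e-08), and TSC22D3, also known as GILZ, rose 1.19-fold (log2 0.25 ± 0.04, adjusted p = 1.47e-04). Adjusted over the list alone, 9 rose and 1 fell. The list passed camera without the pairs (adjusted p = 0.00159) and with them (adjusted p = 1.05e-04), but not with an estimated correlation (adjusted p = 0.344 without and 0.132 with the pairs). Fry in limma with the pairs gave an adjusted p of 0.00717 and without them 0.430.

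Inflammatory genes moved in the same direction. Among 19 tested, 5 rose, IL11 fell and 13 did not pass. Beside VCAM1, the chemokine CXCL8 rose 1.34-fold from 34.6 ± 12.0 to 46.9 ± 17.9 CPM (log2 0.43 ± 0.05, adjusted p = 4.26e-06 in edgeR with the block). CXCL1 rose 1.21-fold (adjusted p = 0.00700), IL1R1 1.17-fold, and PTGS2, a prostaglandin synthase that is induced at ovulation, 1.35-fold (adjusted p = 0.00716). Adjusted over the list alone, 8 rose and 1 fell. Camera gave an adjusted p of 8.11e-04 without and 9.43e-06 with the pairs, and an adjusted p of 0.344 and 0.132 with an estimated correlation. Fry gave an adjusted p of 0.430 and 0.00717. In the blocked fit PTGS2 and CXCL1 did not pass without the pair numbered 10_23. PTGS2 and IL11 were also lost in DESeq2 with the block, and IL11 without the pair numbered 10_28 or 11_5.

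Cell cycle genes moved down with DHT in KGN cells, mainly those of DNA replication. Mitosis members of the list had a median log2 change of -0.042, against -0.13 for replication members, with phases assigned after the data were seen. Of 34 tested, 10 fell, 0 rose and 24 did not pass. The replication licensing factor CDT1 fell to 0.856 of control (log2 -0.22 ± 0.04, adjusted p = 0.00355 in the blocked edgeR fit), the helicase subunit MCM2 to 0.883 (log2 -0.18 ± 0.03, adjusted p = 0.00138), CDC6 to 0.882 (adjusted p = 0.00533) and the transcription factor E2F1 to 0.877 (adjusted p = 0.00611). MCM3, MCM4, MCM5, MCM6, PCNA and TYMS were the others that fell. Adjusted over the list alone, 13 fell and 1 rose. Camera gave an adjusted p of 2.72e-05 without and 2.50e-08 with the pairs, against an adjusted p of 0.686 and 0.132 with an estimated correlation. Fry gave an adjusted p of 0.992 and 0.00717. Without ethanol library 10_28 the unpaired camera result was lost (adjusted p = 0.0567).

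Among matrix and protease genes, 4 of 29 rose and 1 fell in KGN cells. CCN2, a matricellular growth factor, rose 1.29-fold from 999 ± 133 to 1295 ± 217 CPM (log2 0.37 ± 0.03, adjusted p = 4.41e-09 in edgeR with the block), and PLAT, the tissue plasminogen activator, rose by a log2 change of 0.29 (adjusted p = 2.74e-07). THBS1 also rose, and the urokinase gene PLAU fell. Adjusted over the list alone, 7 rose and 2 fell. Camera passed this list with the pairs (adjusted p = 0.0134) and not without them (adjusted p = 0.318), nor with an estimated correlation in the blocked fit (adjusted p = 0.540). It was also lost by fry (adjusted p = 0.0927), with trends on GC content and length removed (0.0726), and without the pair numbered 10_23 (0.111) or 10_28 (0.169). In the insulin and IGF list 4 of 20 rose, among them IGFBP3 (1.16-fold), the insulin receptor INSR (1.16-fold) and PAPPA (1.13-fold), but the list did not pass with the pairs (adjusted p = 0.115). Adjusted over that list alone, 5 rose and 2 fell.

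The androgen response list drawn from prostate cells did not shift in KGN cells. Of its 88 tested genes, 3 rose and 0 fell. These were SAT1 (1.13-fold), LIFR (1.12-fold) and ABCC4 (1.11-fold), and camera with the pairs gave an adjusted p of 0.902. All 3 genes were lost without the pair numbered 11_5, and LIFR and ABCC4 also without the pair numbered 11_1. Adjusted over the list alone, 3 rose and 1 fell. FKBP5, a standard androgen target, stood at 47.9 ± 1.09 CPM with DHT and 47.5 ± 2.35 with ethanol (log2 0.01 ± 0.04, adjusted p = 0.934 in the blocked edgeR fit). The remaining 12 lists had camera adjusted p from 0.0543 to 0.902 with the pairs, and within them, besides genes already named, EGR1, EGR2, NR4A2, VEGFA and DDIT4 rose and ID3 and JUN fell.

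Of the genes named in every case, none passed in KGN cells. KDM6B, which removes methyl groups from histone H3 lysine 27, had a log2 change of 0.16 ± 0.04 with an adjusted p of 0.0643 in the blocked edgeR fit, and EZH2, which adds them, -0.09 ± 0.04 with an adjusted p of 0.402. FOXL2, a granulosa transcription factor, had -0.05 ± 0.03 (adjusted p = 0.573). The aromatase gene CYP19A1 was low, at 0.790 ± 0.527 CPM with DHT and 0.844 ± 0.573 with ethanol. The gonadotropin receptor genes FSHR and LHCGR had 0 counts in the 10 libraries, which allows up to 0.0869 CPM in the shallowest.

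Further genes among the largest changes were RHOU (1.35-fold), SEC31B (1.48-fold) and C4BPB (1.41-fold), which rose, and ID3, SLC38A4, DACT1, CENPQ and IL11, which fell with log2 changes from -0.27 to -0.22. MT-ND6 was 1.55-fold higher, but it lies antisense to other mitochondrial transcripts and the kit does not mark strand, so its value is uncertain. Against a minimum change of 1.2-fold, 2 genes passed in the blocked fit, TMTC1 and VCAM1. Without the pair numbered 11_5 the blocked count was 132 and without the pair numbered 10_23 it was 151, of which 127 and 141 were among the 268. Without the pair numbered 10_28 it was 175, with 152 shared.

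In mouse granulosa cells no gene passed the threshold 18 h after DHT. Among 16689 genes, 0 were called by the edgeR quasi-likelihood test, 450 had an unadjusted p under 0.05 against 834 expected by chance, and DESeq2 and voom also called 0, with 704 and 2544 at that level. On simulated counts 0 of 50 genes changed 1.2-fold were recovered in mouse cells, so this does not exclude changes of the size found in KGN cells. Among the genes with the smallest unadjusted p were Rflnb, Rhob, Ide and Gpat3 in the lower direction and Tmem175, Foxj2 and Sh3d21 in the higher, and none of these passed (adjusted p = 0.993 for each in edgeR). Ide, which encodes insulin-degrading enzyme, stood at 261 ± 70.6 CPM with DHT and 414 ± 76.8 with vehicle (log2 -0.66 ± 0.19). Rflnb stood at 25.8 ± 2.77 and 35.7 ± 6.04 CPM.

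The mouse libraries of both groups differed widely within each group. DHT library 3 and vehicle libraries 2 and 4 lay on the other side of the first principal component, which held 58.0% of the variance, from the remaining 7. Fkbp5 was at 1098 CPM in DHT library 3 and at 1384 and 1162 CPM in vehicle libraries 2 and 4, and between 296 and 457 CPM elsewhere. The group values overlapped. Fkbp5 stood at 506 ± 333 CPM with DHT and 764 ± 472 with vehicle, the luteinizing hormone receptor gene Lhcgr at 291 ± 212 and 566 ± 409, and the aromatase gene Cyp19a1 at 331 ± 212 and 280 ± 185. Fshr, Foxl2, Ezh2 and Kdm6b had log2 changes of 0.17 ± 0.35, -0.09 ± 0.14, -0.02 ± 0.08 and 0.03 ± 0.10. DHT library 3 and vehicle libraries 2 and 4 were also the 3 highest for Lhcgr and the 3 lowest for Cyp19a1 and Fshr. They did not stand apart together for Foxl2, Ezh2 or Kdm6b. Without the 3 libraries, a step chosen after the data were seen, the count of changed genes was still 0, with 954 at an unadjusted p under 0.05.

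**Figure D2:**
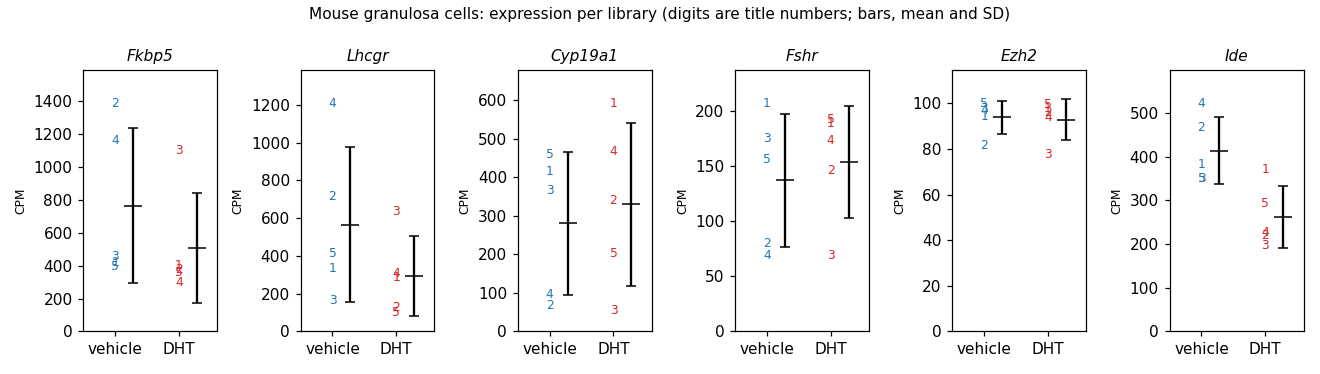
Expression in CPM (vertical axes, from 0) of 6 genes in the mouse libraries, with each library drawn as its title number, vehicle in blue and DHT in red, and the mean and SD of each group (n = 5) beside them. For Fkbp5, DHT library 3 lies at 1098 CPM with vehicle libraries 2 and 4, above the other libraries of both groups.

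As groups, 8 lists lay lower and 1 higher with DHT in mouse cells by camera with the preset correlation, with 0 members of any list past the threshold, over all genes or adjusted over the list alone. None of the 9 held with an estimated correlation, where the smallest adjusted p of any mouse list was 0.680, or by fry, where it was 0.771. Cholesterol synthesis genes had a median log2 change of -0.32 over 25 members (adjusted p = 3.91e-07, against 0.680 with an estimated correlation). Luteal markers had a median of -0.67 over 14 (adjusted p = 0.00283 against 0.680). Among them, the prostaglandin F receptor gene Ptgfr had a mean of 30.5 CPM with DHT and 128 with vehicle. The list member Cyp19a1 went the other way, at 331 ± 212 and 280 ± 185 CPM. Another member, Lhcgr, was highest in DHT library 3 and vehicle libraries 2 and 4, which are split unevenly between the groups. Ptgfr itself did not pass, so its means alone do not show a group difference. Endothelial markers had a median of -0.78 over 14 (adjusted p = 3.96e-05 against 0.680), with Pecam1 at 8.89 and 16.1 CPM. Red cell markers had a median of -0.59 over 7 (adjusted p = 5.63e-04 against 0.680), with Hbb-bs at 49.6 and 75.5 CPM. The lists of androgen response (adjusted p = 0.00326), matrix and proteases (0.00283), hypoxia and glycolysis (0.00489) and endoplasmic reticulum stress (0.00338) were also lower, and interferon response was higher (0.00672), each at 0.680 or 0.686 with an estimated correlation. Single libraries also mattered. Interferon response was lost without DHT library 3 (adjusted p = 0.507), vehicle library 1 (0.181) or vehicle library 3 (0.0572), and hypoxia and glycolysis without DHT library 5 (0.238) or vehicle library 2 (0.868). Without vehicle library 2 the matrix and luteal lists were lost as well (adjusted p = 0.0550 for each). The other 16 mouse lists had camera adjusted p from 0.106 to 0.854.

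**Figure D3:**
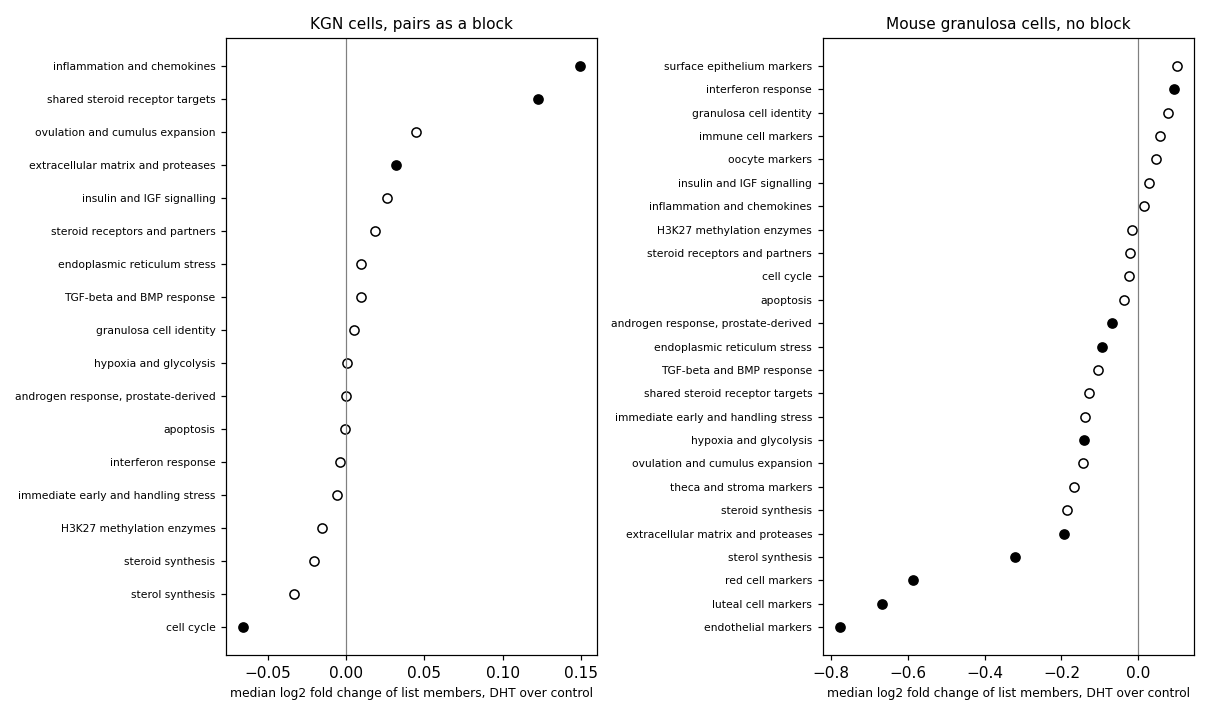
Median log2 fold change of each list's members (horizontal axes, DHT over control) in KGN cells with the pairs as a block (left) and in mouse granulosa cells (right). Filled points passed camera with the preset correlation at an adjusted p under 0.05, and the horizontal scales differ. Inflammation and chemokines lay highest in KGN cells at 0.15 and cell cycle lowest at -0.07, and endothelial markers lay lowest in mouse cells at -0.78.

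Between the systems, no gene had a DHT effect that differed past the threshold. Of 10871 genes, 0 were called by the edgeR test of the difference and 216 had an unadjusted p under 0.05. ERRFI1 had the smallest unadjusted p, with a log2 change of 0.35 in KGN cells and -0.20 in mouse cells (difference -0.56 ± 0.13, adjusted p = 0.9999). Next were SRGAP1, STIL, IGFBP3, RFLNB, NAXD, TPRKB, IDE, TERF2 and USO1, none of which passed. The replicate block within species also gave 0 genes, with 462 at an unadjusted p under 0.05. Of 50 genes simulated with a 1.2-fold difference, 0 were recovered, so small differences are not excluded. A normal approximation from the separate fits called 1 gene, ERRFI1. Across genes, which are not independent replicates, the log2 fold changes of the systems had a Pearson r of 0.109 and a Spearman rho of 0.165, and 57.4% of genes had the same sign. As 0 genes passed in either fit without the pairs, the overlap of calls was 0 and could not be tested.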

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

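Of 114 sets of 5 values of named genes, 8 (7.02%) held a library apart from the rest by Dixon's test, where chance gives about 5%. The test on the 3 mouse libraries was chosen after the results were seen, as were the splits of KGN genes without the pairs, of mouse genes, of the difference between the systems and of the rank correlation.

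In KGN cells KLF9 was at 23.3 CPM in ethanol library 10_28, against 11.9 to 15.1 in the other ethanol libraries, and FKBP5 at 51.5 CPM in the same library, against 45.4 to 47.1. ID3 was at 59.0 CPM in DHT library 10_28 (others 43.3 to 45.9), TSC22D3 at 55.7 CPM in DHT library 10_23 (others 41.0 to 44.3) and PTGS2 at 4.87 CPM in ethanol library 11_1 (others 3.46 to 3.84). In mouse cells DHT library 3 stood apart for Fkbp5 at 1098 CPM (others 296 to 398) and Ezh2 at 77.4 CPM (others 94.0 to 99.6), and DHT library 4 for Sh3d21 at 9.36 CPM (others 5.16 to 6.29).

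The mouse lists were set against the 3 libraries on the far side of the first principal component, of which 2 were vehicle and 1 DHT. By camera with the preset correlation, 9 of the 9 lists stayed past the threshold in the same direction without them. In all, 14 lists then passed. These calls thus did not need the 3 libraries. What moved the lists cannot be told from this, since other splits of all 10 libraries passed as many by the same setting. Fry and an estimated correlation were not run without the 3 libraries. With all libraries, however, 0 of the 9 passed with an estimated correlation (adjusted p = 0.680 or 0.686 in limma) or by fry. Chance stays open, since 38 of 100 splits of the 10 mouse libraries put at least 9 lists past the threshold, and the highest other split reached 15. The splits counted how many lists passed and did not record which, so they do not test any single list. No biological explanation was read from these lists.

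Other splits of the libraries were counted for each comparison. In KGN cells without the pairs the real split called 0 genes, so all 100 splits called at least as many by definition, and the highest other called 475. That split parted 1 of the 5 pairs, as did 27 splits in all, so it may follow differences between pairs. The 13 splits that part all 5 pairs, the real one included, called 0. With the pairs as a block, the real assignment called 268 genes and the highest of the other 15 called 12, so 1 of 16 was as large, too few for a share under 0.05. At an unadjusted p under 0.05 in edgeR the real assignment had 1848 genes, against 752 expected by chance. The highest other assignment had 1811, nearly as many. For lists without the pairs, 69 of 100 splits reached the real 3 and the highest reached 9, so chance cannot be excluded over all splits. Among the 13 that part all 5 pairs the real one put 3 lists past the threshold and the highest other 1, which are too few splits for a share under 0.05. With the pairs, 3 of 16 reached the real 4, and the highest other was 4. Other assignments thus matched the real list count, and chance is not excluded for it. Those that matched it had 1 pair swapped and kept the real direction in the other pairs. With 2 pairs swapped the highest was 3 lists. In mouse cells all 100 splits, real one included, called 0 genes. For the difference between the systems the real split called 0 and the highest other 160, so 100 of 100 were as large, again by definition. The correlation of 0.109 was reached by 5 of 100 splits, the highest other being 0.153, so chance is not excluded at 0.05. The Spearman rho of 0.165 was reached by 1 of 100 splits, the highest other being 0.164, which alone would exclude chance at 0.05. That count was added after the one for r, another split had a rho of -0.170, and without KGN DHT library 12_4 the real rho was 0.115, so the relation was left open. Most KGN splits behind both counts parted fewer than 5 pairs, so they carry pair differences that the real split does not.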

How the results depend on the processing

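The pairing decided the KGN result. Without it, counts of changed genes were 0 with all planned settings but DESeq2 (2), no filter (1) and 1 surrogate variable (1), and 0 with any library left out. The replicate block gave 268 genes in edgeR and 175 in DESeq2; the block was planned, but its own alternatives were added after the data were seen. Within the block the count was 2 against a 1.2-fold minimum, 652 with the GC and length trends removed, and 0 without the block. With a pair left out it ran from 132 (without 11_5) to 246, with 151 without 10_23 and 175 without 10_28. None of the 268 turned direction in these fits where tested. Of 38 named genes past the threshold with the block, 26 also passed in DESeq2 and with each pair left out, and 12 did not, namely ABCC4, CENPQ, CXCL1, EGR2, GMNN, IL11, LIFR, NR4A2, PAPPA, PTGS2, SAT1 and SLC38A4. Without the pairs 3 KGN lists passed, 0 with an estimated correlation or by fry, and 2 to 6 with a library left out, the 6 without ethanol library 12_4 and again without DHT library 11_5. With the replicate block 4 passed, and 0 with an estimated correlation. In mouse cells the gene count was 0 in 21 alternatives, the replicate block included, whose numbers do not pair the samples (2 of 5 treated libraries were closest to their own number). Of 9 mouse lists 0 passed with an estimated correlation, 0 by fry and 0 by fry with the block, and 14 passed without the 3 libraries that stand apart. The difference between the systems gave 1 gene from separate fits and 0 otherwise. The correlation was 0.162 among genes with at least 5 CPM and 0.213 among those changed in KGN cells with the block; no gene passed in the planned fits, so the planned subset of changed genes could not be run. The cause of these shifts was not tested. Several small changes that never passed also turned sign. FKBP5 in KGN cells ran from -0.0022 to 0.045 with a library left out and from -0.0021 to 0.043 with a pair left out, and was -0.011 with the trends removed. CYP19A1 ran from -0.37 to 0.25. In mouse cells, with a library left out, Ezh2 ran from -0.065 to 0.042, Cyp19a1 from -0.092 to 0.51, Kdm6b from -0.024 to 0.12 and Fshr from -0.0033 to 0.37. Ezh2 was 0.0082 with upper-quartile factors. With voom Cyp19a1 was -0.021 and Kdm6b -0.040, with a surrogate variable Cyp19a1 was -0.077 and Fshr -0.0055, and without the 3 libraries Cyp19a1, Kdm6b and Fshr were -0.048, -0.052 and -0.032. Depth limits genes with few counts, such as CYP19A1 in KGN cells.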

Other observations

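The tests on lists, on GC content and length, on phases of the cell cycle and on the shared list in this part were chosen after the results were seen. Some transcripts that tend to stay in the nucleus or keep introns were higher with DHT in KGN cells. A list of 30 such transcripts was drawn up after its leading members had been seen, so its count is not independent evidence. In the blocked edgeR fit 12 of the 30 rose, 0 fell and the others did not pass, with a median log2 change of 0.12. The long noncoding RNAs NEAT1 (1.27-fold, adjusted p = 9.21e-05), MEG3 (1.25-fold, adjusted p = 6.73e-05) and MALAT1 (log2 0.29, adjusted p = 0.00188) rose, as did OGT, which encodes the O-GlcNAc transferase (1.16-fold, adjusted p = 3.28e-04).

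Across the 9759 better expressed genes of known length, blocked log2 changes of KGN cells correlated with transcript length (Spearman rho 0.352) and GC content (rho -0.191), though single pairs ran from -0.117 to 0.477 for length and from -0.553 to 0.471 for GC content. With both trends removed per library the blocked values were 0.0757 and -0.0396. The list's median was then 0.890 times its earlier value and 16 members rose. Since the list was drawn up after its leading members had been seen, these values cannot decide whether the trends were the whole cause. A handling difference that both systems share may still contribute, and the mouse list had a median log2 change of 0.28, but an exact permutation test over the 126 splits of the mouse libraries, which took the place of a fry test that did not pass either, gave p = 0.190. In this design a handling difference that follows the treatment cannot be told apart from a response to DHT, whatever the number of libraries.

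DNA replication genes were lower with DHT in KGN cells while mitosis genes showed less change. On lists drawn up after the data were seen, 15 of 34 replication genes fell (median log2 change -0.13) and 0 of 28 mitosis genes passed (median -0.03, above 0 in 1 of 5 pairs). Removing the GC and length trends left the replication median at 0.990 times its value. The choice of this list after the data were seen keeps that ratio from deciding on the trends. The cell cycle list fixed in advance still passed camera in the blocked fit with the trends removed. Within the cell cycle list fixed in advance, the 19 mitosis members had a median of -0.042 (SD 0.054 across members), and 14 of the 19 were lower. This median lay 0.086 above that of the 14 replication members (-0.13). The gap cannot decide on fewer cycling cells of every phase, since the phases were assigned from lists drawn up after the data were seen. Fewer cycling cells need also not lower both sets equally. A smaller share of cycling cells as part or all of the change, and a difference between wells that follows the treatment, were not excluded.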
